A study of Mus musculus with 6 samples.

How the data were processed

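Total RNA of 6 mouse mammary epithelial cell cultures, 3 WT and 3 without Jarid1b (Kdm5b), was labelled as biotinylated cRNA and hybridised to Illumina mouse bead arrays, per the labels' protocols. The deposited intensity values are probe brightness on each array without normalisation, per the file headers, and no background had been subtracted from them. The deposited detection p-value of each probe compares it with the negative control beads of the same array, per the file headers. A value table by the authors holds the same arrays on a log2 scale, with the same sorted values in every column (median 6.75 in each), which shows quantile normalisation over the 6 arrays. The ranks of each column equal those of that array's raw intensities (Spearman correlation 1), so its direction is known and its genes are not centred. Its low end is raised against plain log2, and the transform behind that is not given in the sources used here. GenomeStudio and lumi are named in the submitters' processing notes, with versions and roles not given in the sources used here.

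Raw intensities and detection p-values were normalised in R 4.3.3 with neqc of limma 3.58.1, which corrects background from the detection p-values, adds an offset of 16, normalises by quantiles and takes log2. A probe entered the test where its detection p was under 0.05 on at least 3 of the 6 arrays, which 17920 probes met. Probe names came from the platform annotation, updated through a gene table of the mouse assembly GRCm38.p6. Of 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 are unnamed here. A gene was its probe with the highest mean log2 value over all arrays, giving 10419 genes, of which 3661 had more than 1 tested probe. No genome build is named by the files, so positions served only to find which genes neighbour Kdm5b. All 6 array columns and their detection columns belong to a sample. The number of columns with no sample was 0.

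KO was compared with WT by lmFit and eBayes of limma, two-sided, without a term for the pair letter, and p-values were adjusted by the Benjamini-Hochberg method over genes with a threshold of 0.05. A bound written as at least N-fold is the bright group's mean against the mean, over the dim group's arrays, of the higher of the lowest signal among detected probes and the dim probe's own signal. It takes group means after the main background correction and leaves out their spread. The fixed lists cover cell types, pathways and JARID1B biology, 26 in all, and 22 had at least 5 tested genes. Camera tested each list against all other genes with a preset correlation of 0.01 and again with an estimated one, and fry tested direction, with adjustment over the 22 lists. For each list, members were also adjusted over the list alone. Genes within 20 Mb of Kdm5b were compared with all other genes by Fisher's exact test, two-sided, on the share with an unadjusted p under 0.05.

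Named genes followed a rule. Kdm5b was named first, then up to 12 genes per direction that passed the threshold without overlap of the groups, ordered by size. Directions with fewer than 6 such genes were filled up to 6 with the smallest unadjusted p without overlap, and these are said not to have passed. Each list gave up to 4 members that passed over all genes or over the list alone, or the 2 with the smallest p where none passed. Esr1, Pgr, Foxa1, Gata3, Elf5, Krt5, Krt14, Krt8 and Krt18 were always named, and unnamed probes, Riken clones and Gm or LOC symbols were counted only. Other probes of a named gene are given where they differ in sign or call. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

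The pair letters come from the sample titles, and the labels speak of pairs of cultures. Arrays with the same letter deviated together from their group means, with correlations of 0.352, 0.490 and 0.720 for pairs A, B and C. WT replicate A with KO replicate B, not a pair, gave 0.423, so the values set pair C apart and do not tell the letters A and B from each other. The fit with the pair letter as a replicate block was an alternative. Further alternatives were no background correction, the authors' value table, median scaling, an offset of 50, other detection filters, each probe on its own, the mean of a gene's probes, eBayes with trend and robust settings, array weights, omission of each array, other windows around Kdm5b and other thresholds. The use of pairs A and B only, and the 50 Mb window with an unadjusted p under 0.01, were chosen after seeing the data.

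The test was tried on simulated data, in 5 runs over 10419 genes for KO against WT, with 100 genes changed per size. The data were made from the real arrays' means, their fitted pair shifts and the spread left after genotype and pair. Without the pair term the test recovered 4% of the 2-fold and 60.2% of the 4-fold changes with 0.4 false calls per run. With the pair as a replicate block it recovered 30.8% and 74.4% with 4 false calls per run. Because pair shifts were planted, the higher recovery with the block was built into the runs and says nothing on which fit suits the real arrays. The slope of fitted on true changes was 0.996, and a list shifted by 0.5 on the log2 scale was called in 5 of 5 runs. The noise of each gene was drawn independently of other genes. In the real arrays the estimated correlation was 0.53 in the shifted list, oxidative phosphorylation, and 0.85 in the proliferation list. The runs therefore cannot show how camera with a preset correlation behaves where genes of a list move together.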

Results

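Gene expression was measured on Illumina mouse bead arrays in cultured mammary epithelial cells, the cells that line the ducts and alveoli of the mammary gland. The cultures came from wild-type (WT) mice and from mice without Jarid1b (KO), the older symbol of Kdm5b, which encodes a demethylase that removes methyl groups from lysine 4 of histone H3. The series holds 3 WT and 3 KO arrays, lettered A, B and C in each genotype, from early-passage cultures harvested before confluence. Each array carried 45281 probes, and 17033 to 18686 of them were detected per array at a detection p under 0.05. The median raw intensity per array lay between 95.3 and 100.7. The labels speak of pairs of cultures and do not say that each culture came from its own animal, so the p-values below measure only the spread between these samples, which may be technical. The small number of arrays limits the precision of every value.

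The arrays did not separate by genotype on the first principal component, which held 56.5% of the variance and set both arrays of pair C apart from the other arrays. The second component, with 18.9%, set the KO array of pair A apart. The WT arrays of pairs A and B were the most alike, with a correlation of 0.992 across probes and a standard deviation of 0.18 for the log2 difference of bright probes. The next closest arrays, WT and KO of pair B, had a standard deviation of 0.31.

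**Figure D1:**
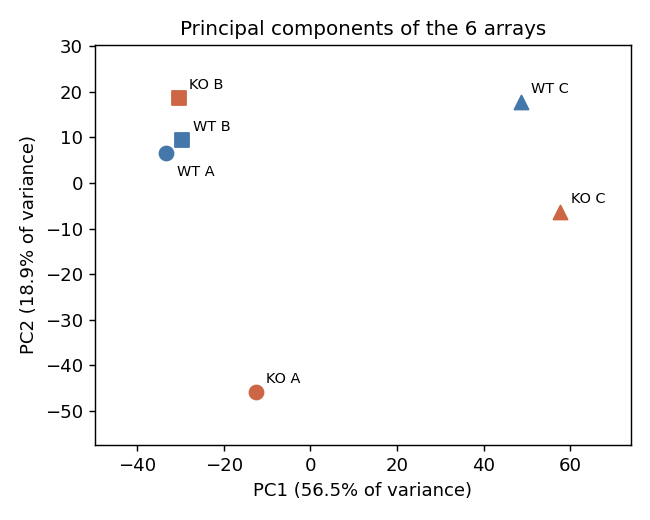
Each point is an array placed by its first (horizontal, 56.5% of the variance) and second (vertical, 18.9%) principal component in arbitrary units, blue for WT and orange for KO, with circles for pair A, squares for pair B and triangles for pair C. Both arrays of pair C lie at the right and the KO array of pair A lies lowest.

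Kdm5b, the targeted gene, fell in the KO cultures. Its brightest probe read 6.85 ± 0.24 (log2 intensity, SD, n = 3) in WT and 4.39 ± 0.05 (SD, n = 3) in KO, a log2 change of -2.46 (SE 0.18, limma adjusted p = 0.0122). The KO value was not above background on any KO array, so the transcript was at least 4.94-fold lower. The other Kdm5b probes had log2 differences of -2.35 (SE 0.18) and -0.90 (SE 0.17), and neither was detected on a KO array. Where these probes lie relative to the deleted part of the gene is not given in the sources used here, and a probe outside that part would check nothing. The call was lost in limma without WT replicate A, KO replicate A, WT replicate B, KO replicate B or KO replicate C, with log2 values of -2.34, -2.46, -2.45, -2.53 and -2.41 and adjusted p = 0.125, 0.0965, 0.186, 0.113 and 0.0636. It was also lost on the authors' own value table, where the log2 difference was -0.89 (adjusted p = 0.153), and adjusted p over all alternatives ranged from 0.00148 to 0.186.

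The comparison of KO with WT asks which probe signals differ between the genotypes. Besides Kdm5b, Csrp1 and Cops8 passed the test among 10419 genes. Both lie on chromosome 1, Csrp1 within 5 Mb and Cops8 within 50 Mb of Kdm5b, and each had 1 tested probe. For such genes a changed transcript cannot be told apart from a sequence variant under the probe. Csrp1, which encodes a LIM-domain protein of the actin cytoskeleton, rose from 4.75 ± 0.12 to 11.75 ± 0.38 (log2 intensity, SD, n = 3 each), a log2 change of 7.0 (SE 0.23) or 128-fold, with limma adjusted p = 7.97e-05. Its WT value lay close to the dimmest detected probes, so the size depends on the treatment of background, with log2 changes of 4.84 without background correction, 4.91 on the authors' value table and 5.83 with an offset of 50. Cops8, a subunit of the COP9 signalosome, rose by 4.22 on the log2 scale (SE 0.40, adjusted p = 0.0495) and was at least 16.2-fold higher in KO, since it was not detected on any WT array. In total 3 genes had an adjusted p under 0.05 in limma, 2 higher and 1 lower in KO, and all 3 differed by at least 2-fold. At an unadjusted p under 0.05 there were 338 genes, 155 higher and 183 lower, where 521 would be expected of independent arrays without any difference. With each array scaled to its median in place of quantiles, that split was 61 higher and 261 lower. The unadjusted count was 159 without WT replicate A, 162 without WT replicate B, 764 without KO replicate B and 554 without WT replicate C. More genes were higher than lower without KO replicate A (243 and 147), without KO replicate B (457 and 307) and with array weights (639 and 519). With the pair letter as a replicate block the unadjusted count was 904, and the same 3 genes had an adjusted p under 0.05. The groups did not overlap for 862 genes (8.27%), where 10% would be expected of exchangeable arrays. The arrays of pair C deviated together (correlation 0.720), so for the fit without the pair term neither 521 nor 10% measures chance here. These counts therefore do not show that the genotypes differed less than by chance. The call of Cops8 was lost in 11 of 17 alternatives, among them the authors' table (log2 difference 2.13, adjusted p = 0.596) and every omission of a single array except KO replicate C, with adjusted p from 0.000537 to 0.611 over all alternatives. Without WT replicate A, KO replicate A, WT replicate B, KO replicate B and WT replicate C the log2 difference of Cops8 was 4.21, 3.95, 4.26, 4.03 and 4.16.

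The genes of this paragraph did not pass the threshold and are given as values. Ipo9, which encodes a nuclear import receptor, read 7.83 ± 0.13 in WT and 5.17 ± 0.56 in KO (SD, n = 3 each), a log2 difference of -2.66 (SE 0.29, adjusted p = 0.0827). It passed without KO replicate A, at -2.95 (adjusted p = 0.0344), and with array weights, at -2.61 (adjusted p = 0.0145). The log2 difference was 1.92 (SE 0.28) for Thap4, 1.35 (SE 0.21) for the basement membrane collagen gene Col15a1 and 1.27 (SE 0.21) for Ddah1, an enzyme that degrades methylated arginines. Eif4e2, which encodes a cap-binding protein, differed by 1.22 (SE 0.19) at its brightest probe and by -0.37 and -0.04 at its other probes. Among genes with lower values in KO, Wdfy1 differed by -1.12 (SE 0.19), Dnajc12 by -1.13 (SE 0.20), the mitochondrial carrier gene Slc25a36 by -0.98 (SE 0.17) and Nckap5 by -1.67 (SE 0.34). Nckap5 was detected on only 1 of 3 KO arrays, so the size of its difference is limited by background. The naming rule took only genes whose KO and WT values did not overlap, and adjusted p was 0.489 or higher for all but Ipo9.

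**Figure D2:**
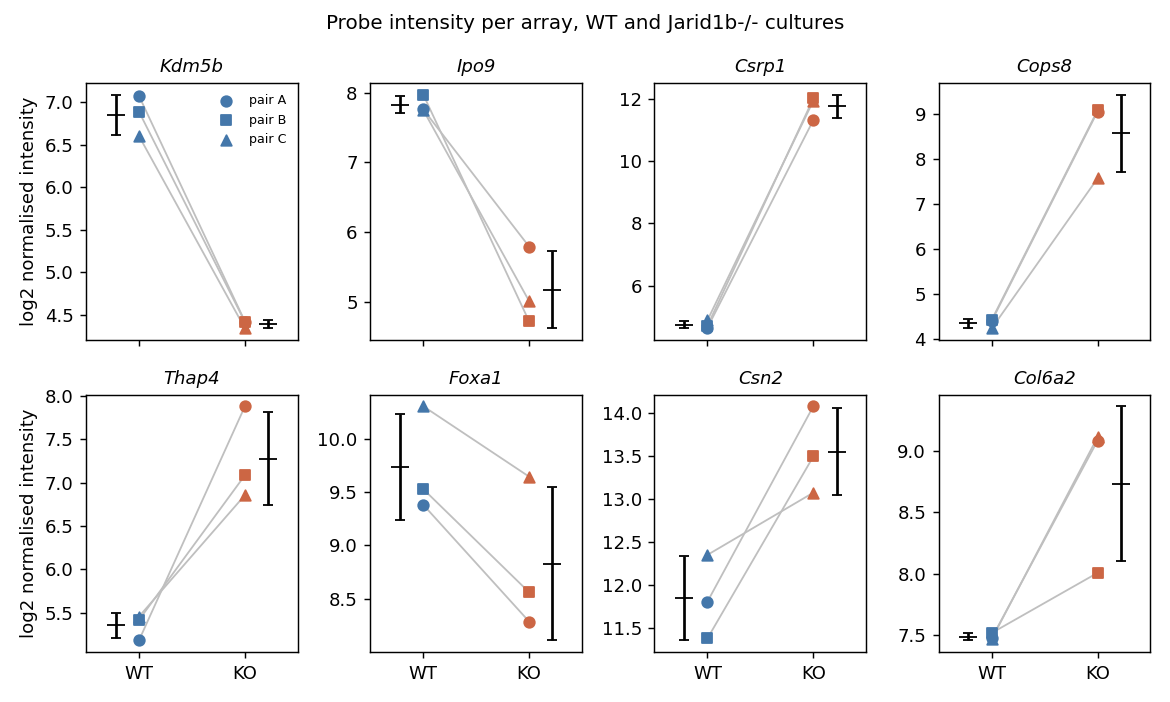
Normalised log2 intensity (vertical axis, a separate range in each panel) of 8 genes on each of the 3 WT (blue) and 3 KO (orange) arrays, with lines joining arrays of the same pair letter and black bars giving the mean ± SD (n = 3). Csrp1 moved from 4.75 to 11.75 and Cops8 from 4.35 to 8.57. Foxa1 differed by -0.91 with overlapping groups, and by -1.10, -0.97 and -0.66 within pairs A, B and C.

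Csrp1 and Ipo9 lie within 5 Mb of Kdm5b on chromosome 1 in the GRCm38.p6 annotation, Nckap5 within 20 Mb, and Cops8, Thap4 and Eif4e2 within 50 Mb. Within 20 Mb of Kdm5b, 8 of 105 tested genes (7.62%) had an unadjusted p under 0.05, against 329 of 10300 genes elsewhere (3.19%). Kdm5b itself was left out of this count. The odds ratio was 2.50 (95% interval 1.04 to 5.18, Fisher's exact test, two-sided, p = 0.0205). Csrp1 was the only gene called in that window besides Kdm5b. Other genes counted in the window were Steap3 (log2 difference 0.70), the chemokine receptor gene Cxcr4 (1.39), Cd55 (-0.60), Pfkfb2 (-0.74) and Plekha6 (-0.80), all named after their values were seen. The exact test missed 0.05 without KO replicate A (odds ratio 2.15, p = 0.0606), KO replicate C (1.89, p = 0.11) or WT replicate C (1.68, p = 0.127), and on the authors' table (2.12, p = 0.0621). The odds ratio was 4.80 without WT replicate A, and the exact p ranged from 1.37e-05 to 0.291 over all alternatives. The lowest came from the 50 Mb window at an unadjusted p under 0.01, a setting chosen after seeing the data.

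Genes of hormone-sensing luminal cells, the cells that carry the receptors for oestrogen and progesterone, had lower values in KO. Of 12 tested members 11 had a negative log2 difference, with a median of -0.41 and medians of -0.54, -0.35 and -0.35 in pairs A, B and C. Foxa1, a pioneer transcription factor of luminal cells, differed by -0.91 (SE 0.41), the ETS factor Spdef by -0.67 (SE 0.20), Pgr, the progesterone receptor, by -0.53 (SE 0.26), Esr1, the oestrogen receptor, by -0.27 (SE 0.35), and Gata3 by -0.20 (SE 0.23). Esr1 had no common direction, with -0.95, -0.06 and 0.20 in pairs A, B and C. The list was called lower by limma's camera with a preset correlation (adjusted p = 0.000159), and not with an estimated one (adjusted p = 0.425 with an estimated correlation). The median was -0.27 without KO replicate A, -0.27 without WT replicate B, -0.20 without background correction and -0.21 on the authors' table. No member passed over all genes and 0 passed adjusted over the list alone, with 1 at an unadjusted p under 0.05. With the pair letter as a replicate block 5 members fell adjusted over the list alone, among them Foxa1 (adjusted p = 0.0109) and Spdef (adjusted p = 0.0344). Foxa1, Gata3 and Esr1 are genes that the study may have picked on these samples, so their counts are not independent evidence of a direction. In the pan-luminal list, 14 of 15 members had a negative difference, with a median of -0.26, and 0 passed over all genes or adjusted over the list alone. The tight junction gene Cldn4 differed by -0.62 (SE 0.31), Rab25 by -0.43 (SE 0.18), and the keratin genes Krt18 and Krt8 by -0.46 (SE 0.26) and -0.21 (SE 0.18). The pan-luminal list was called by camera (adjusted p = 0.00268; adjusted p = 0.434 with an estimated correlation) and not without KO replicate A (median -0.12, adjusted p = 0.173), while the median was -0.41 without KO replicate B.

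Csn2, which encodes the milk protein beta-casein, rose within the luminal progenitor and alveolar list. Its log2 intensity was 11.84 ± 0.49 in WT and 13.54 ± 0.50 in KO (SD, n = 3 each), a change of 1.70 (SE 0.34), with adjusted p = 0.0252 adjusted over the list alone and adjusted p = 0.954 over all genes. Of 18 tested members, 1 passed adjusted over the list alone and 0 passed over all genes. With the pair letter as a replicate block 4 members passed adjusted over the list alone. By pair the list medians were 0.17, 0.40 and -0.30 in A, B and C, with 10, 17 and 6 of the 18 members positive. The list as a whole had a median of 0.08, or -0.03 with median scaling, with 11 members higher, and camera gave adjusted p = 0.0777, or 0.0425 with the replicate block and 0.0459 with median scaling. With an estimated correlation it gave 0.478, or 0.608 with the replicate block. With the preset one it gave 0.0144 without KO replicate C (median 0.06) and 0.00945 without WT replicate C (median 0.31), 0.0195 with array weights and 0.000481 with pairs A and B only. It did not pass without WT replicate B (median -0.08, adjusted p = 0.305), WT replicate A (median 0.03, adjusted p = 0.129), KO replicate B (adjusted p = 0.616) or KO replicate A (adjusted p = 0.0585). Elf5, the transcription factor of alveolar progenitors, differed by 0.07 (SE 0.49), or -0.04 with median scaling. Its 3 probes did not share a sign.

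Basal and myoepithelial genes had no common direction. Of 17 members 9 were higher, the median was 0.01, or -0.08 with median scaling, and camera gave adjusted p = 0.254. Omission of 1 array moved the median from -0.14 without KO replicate C to 0.26 without WT replicate C (adjusted p = 0.0736), and it was 0.24 with array weights (adjusted p = 0.0946). The basal keratin genes Krt5 and Krt14 differed by 0.07 (SE 0.56; -0.04 with median scaling) and -0.32 (SE 0.31), while the mesenchymal filament gene Vim differed by 0.46 (SE 0.15) and the matrix gene Sparc by 0.65 (SE 0.32). For Krt5 the difference was 1.32 in pair A, -0.99 in pair B and -0.13 in pair C. The epidermal differentiation list had a median of -0.08 over 10 members (adjusted p = 0.586), with -0.26 (SE 0.25) for Cnfn and -0.21 (SE 0.21) for Krt6a. That median ranged from -0.20 to 0.06 when an array was omitted. In both lists 0 members passed over all genes and 0 adjusted over the list alone, and 1 basal member and 0 epidermal members had an unadjusted p under 0.05 in limma.

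Genes of fibroblasts and stroma had higher values in KO, with all 18 tested members positive and a median of 0.51. Col6a2, a collagen VI chain, differed by 1.25 (SE 0.31), Loxl1, an enzyme that crosslinks elastin, by 1.06 (SE 0.29), Col5a1 by 0.84 (SE 0.23) and the growth factor receptor gene Pdgfrb by 0.53 (SE 0.16). These 4 were among the 5 members that rose adjusted over the list alone (adjusted p = 0.048 for each of the 4), where 0 rose over all genes. With the pair letter as a replicate block 8 members rose adjusted over the list alone. A second Col6a2 probe differed by 0.01. Camera called the list higher (adjusted p = 2.12e-10), and not with an estimated correlation (adjusted p = 0.425 with an estimated correlation). The median was 0.17 without background correction, 0.18 on the authors' table and 0.74 with detection p under 0.01 on all 6 arrays. The shift was uneven across pairs, with medians of 0.73 in pair A, 0.02 in pair B and 0.94 in pair C. The epithelial-mesenchymal transition and TGF-beta list had a median of 0.10 over 18 members, with Fn1, the fibronectin gene, at 0.95 (SE 0.42) and a second Fn1 probe at -0.05. Camera gave that list adjusted p = 0.043, then 0.434 with an estimated correlation, 0.134 with the replicate block and 0.0706 with median scaling. It gave 0.0991 without a detection filter, 0.0534 with trend and robust settings, 0.717 with array weights and 0.649 with pairs A and B only. The call was also lost without KO replicate A (median 0.24, adjusted p = 0.0557), KO replicate B (median -0.01, adjusted p = 0.455) or WT replicate C (median 0.03, adjusted p = 0.955), and the median was 0.17, 0.19 and 0.28 without WT replicate A, WT replicate B and KO replicate C. The list of matrix metalloproteinases and branching genes had a median of 0.22 with 16 of 20 members higher, among them Fgf10 at 0.96 (SE 0.48) and Msx1 at 0.50 (SE 0.28). Its adjusted p was 0.01, or 0.425 with an estimated correlation, and 0.185 without WT replicate C (median 0.13). It was 0.059 without a detection filter, 0.105 with array weights (median 0.10) and 0.114 with pairs A and B only (median 0.12). In both of these lists 0 members passed over all genes and 0 adjusted over the list alone, and 1 and 0 members had an unadjusted p under 0.05 in limma.

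Proliferation genes were higher in the KO arrays of pairs A and C and not in pair B. All 22 tested members were positive in the group means, with a median of 0.77, and the medians were 1.81 in pair A, -0.24 in pair B and 0.58 in pair C. Without KO replicate A, KO replicate C or KO replicate B the group median was 0.43, 0.45 and 1.37. It was 0.30 without background correction and 0.31 on the authors' table. The replication licensing gene Mcm3 differed by 0.79 (SE 0.31) and the ribonucleotide reductase gene Rrm1 by 1.03 (SE 0.45). Camera called the list (adjusted p = 1.13e-08), and not with an estimated correlation (adjusted p = 0.434 with an estimated correlation). None of the members passed over all genes and 0 passed adjusted over the list alone, with 1 at an unadjusted p under 0.05 in limma. The list of cell cycle inhibitors and p53 response genes had a median of 0.13 over 17 members (adjusted p = 0.159), with 0.74 (SE 0.24) for Cdkn1c and 0.38 (SE 0.22) for Phlda3. Its median ranged from 0.06 to 0.14 when an array was omitted and was 0.006 with median scaling. Oxidative phosphorylation genes had a median of 0.15 with 17 of 22 members higher, including Ndufb9 at 0.46 (SE 0.19) and Ndufa2 at 0.35 (SE 0.20). The medians were 0.41, -0.02 and 0.11 in pairs A, B and C, with 21, 10 and 16 members positive. Camera gave adjusted p = 0.00268, then 0.478 with an estimated correlation, 0.175 without KO replicate A (median 0.11) and 0.0915 without KO replicate C (median 0.13). The median was 0.32 without KO replicate B, 0.27 without WT replicate C and 0.04 with median scaling. In these last lists 0 members passed over all genes and 0 adjusted over the list alone, and 1 member of each had an unadjusted p under 0.05 in limma.

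Immune and endothelial genes, markers of other cells that a primary culture could hold, had medians that differed mainly within single pairs. Immune cell genes had a median of 0.61 over 12 members, with 1.57 in pair C, 0.06 in pair A and -0.10 in pair B. Camera gave adjusted p = 0.0411, then 0.535 with an estimated correlation and 0.199 without WT replicate B (median 0.38), and the median was -0.32 without KO replicate C (adjusted p = 0.0467). The call was also lost without a detection filter (median 0.15, adjusted p = 0.0722), with detection p under 0.01 on all 6 arrays (median 0.38, adjusted p = 0.0509) and with pairs A and B only (adjusted p = 0.649). The median was 1.05, 1.08 and 0.98 without KO replicate A, KO replicate B and WT replicate C. The lysozyme gene Lyz2 differed by 0.85 (SE 0.47) and the B-cell receptor gene Cd79b by 1.06 (SE 0.87). For Cd79b the difference was 0.24, 0.24 and 2.69 in pairs A, B and C. Endothelial genes were all positive, 11 of 11, with a median of 0.35, and pair B alone had 0.99. The tight junction gene Cldn5 differed by 0.62 (SE 0.28) and Tie1, a vascular receptor, by 0.60 (SE 0.31). Camera gave adjusted p = 0.00109, then 0.434 with an estimated correlation and 0.599 without KO replicate B (median 0.04), and the median was 0.61 without KO replicate A. In the immune and endothelial lists 0 members passed over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 in limma. The adipocyte list had 4 tested members, too few for a list test. Lpl differed by 1.24 (SE 0.42) and Pparg by -0.58 (SE 0.39), and 0 of the 4 passed adjusted over the list alone or over all genes. With the pair letter as a replicate block, Lpl (adjusted p = 0.00242) and Pparg (adjusted p = 0.0339) passed adjusted over the list alone. The interferon response list had a median of -0.14 over 17 members (camera adjusted p = 0.124, or 0.535 with an estimated correlation), with Oas2 at -0.39 (SE 0.27) and Bst2 at -0.33 (SE 0.25). It passed without WT replicate A (median -0.12, adjusted p = 0.0291) or KO replicate B (median -0.25, adjusted p = 0.00619), and with array weights (adjusted p = 0.0304). The median was 0.00 without KO replicate A (adjusted p = 0.788) and -0.05 without WT replicate B (adjusted p = 0.265). Inflammatory chemokine and cytokine genes had a median of 0.13 over 20 members (camera adjusted p = 0.481, or 0.832 with an estimated correlation), with 0.68 (SE 0.42) for Cxcl10 and 0.98 (SE 0.75) for Saa3. The latter list passed as higher without WT replicate A (median 0.69, adjusted p = 0.026) or WT replicate B (median 0.67, adjusted p = 0.00809), and as lower without WT replicate C (median -0.55, adjusted p = 0.00597), with array weights (median -0.44, adjusted p = 0.0344) or with pairs A and B only (median -0.24, adjusted p = 0.0452). In these lists 0 members passed over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05 in limma.

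**Figure D3:**
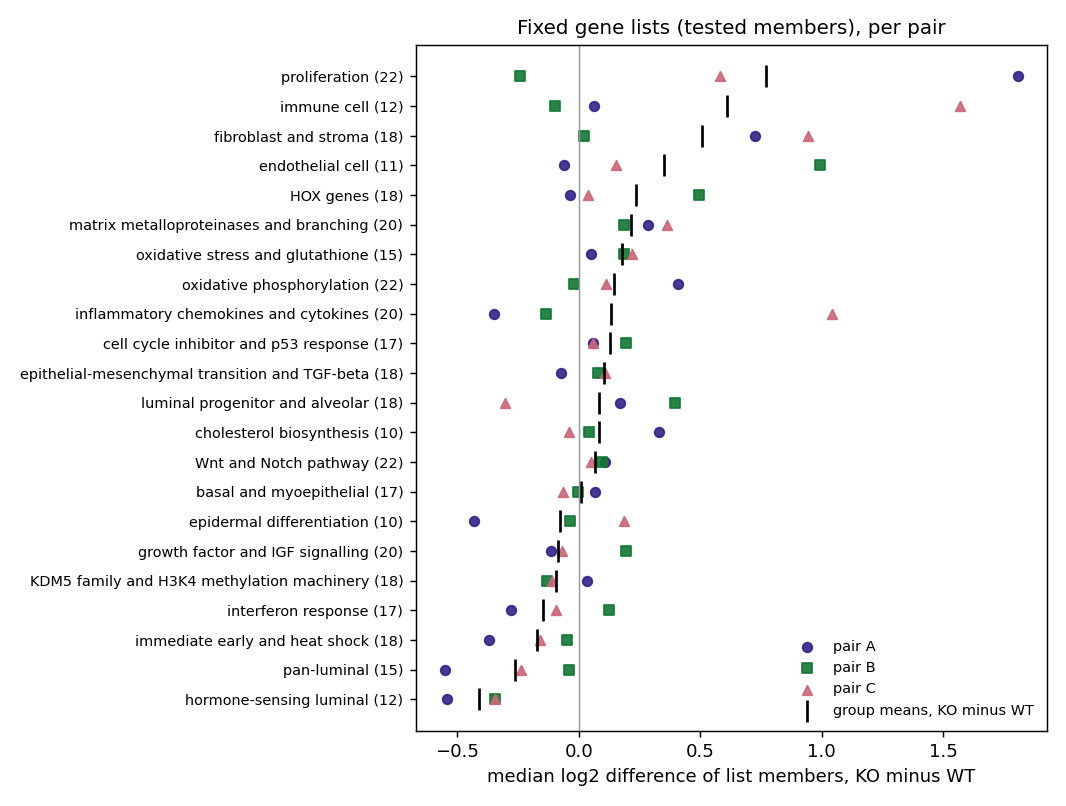
Median log2 difference, KO minus WT, of the tested members of each fixed gene list (horizontal axis; list names with member counts on the vertical axis), for pair A (circles), pair B (squares) and pair C (triangles), with black bars for the difference of the group means. The hormone-sensing luminal list lies below 0 in all 3 pairs, and the proliferation list spans -0.24 to 1.81.

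In the list of KDM5 genes and the H3K4 methylation machinery, Kdm5b fell and no other of the 18 members passed over all genes or adjusted over the list alone. The median was -0.09 and camera gave adjusted p = 0.228, with medians from -0.11 to 0.004 when an array was omitted. HOX genes had a median of 0.24 with 14 of 18 members higher, including Hoxc9 at 0.40 (SE 0.17) and Hoxb4 at 0.43 (SE 0.25). The median was highest in pair B, at -0.04, 0.50 and 0.04 in pairs A, B and C, with 8, 16 and 13 members positive. The endothelial list was also highest in pair B (0.99). Hoxc9 differed by 0.14, 0.39 and 0.66 in pairs A, B and C, most in pair C. Camera gave the HOX list adjusted p = 0.00615, then 0.434 with an estimated correlation and 0.599 without KO replicate B (median 0.04). Its median was 0.39 without KO replicate A. Without a detection filter adjusted p was 0.119 (median 0.05), and the median was 0.09 without background correction. Of 4 tested genes held to be repressed by JARID1B in MCF-7 breast cancer cells, Cav1 differed by 0.33 (SE 0.26) and Hoxa5 by 0.30 (SE 0.30), and 0 passed. Tdrkh was the only tested member of the germline list, at 0.52 (SE 0.19, adjusted p = 0.0269 over the list alone, which is then unadjusted), with -0.15 at its second probe.

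The growth factor and IGF signalling list had a median of -0.08 over 20 members (adjusted p = 0.899), with the receptor gene Fgfr2 at -0.74 (SE 0.29) and Igf1 at 0.45 (SE 0.17). Its median ranged from -0.19 to 0.01 when an array was omitted. The 4 probes of Fgfr2 were all lower in KO, from -0.74 to -1.25. The Wnt and Notch list had a median of 0.07, or -0.05 with median scaling, over 22 members (adjusted p = 0.267), with 0.60 (SE 0.23) for the Wnt antagonist gene Sfrp1 and 0.43 (SE 0.20) for the Wnt target Axin2. Omission of 1 array gave that list medians from 0.05 to 0.17. Immediate early and heat shock genes had a median of -0.17, with Jun at -0.53 (SE 0.39) and Junb at -0.31 (SE 0.31). Camera gave that list adjusted p = 0.0893, or 0.00593 with the pair letter as a replicate block, 0.0304 with array weights and 0.0446 with pairs A and B only. With an estimated correlation it was 0.434, or 0.608 with the replicate block. Omission of any 1 array gave no call, with medians from -0.31 without KO replicate B to -0.10 without KO replicate C and adjusted p from 0.0516 to 0.518. The median was -0.11 without WT replicate B and -0.11 without WT replicate C. Oxidative stress and glutathione genes had a median of 0.18 (adjusted p = 0.0606, or 0.0163 with the replicate block; 0.434 and 0.608 with an estimated correlation), with Nqo1 at -0.63 (SE 0.39) and Gstm2 at 0.48 (SE 0.32). Without WT replicate A, WT replicate B or KO replicate C that list had medians of 0.23, 0.26 and 0.25 and adjusted p = 0.0137, 0.0364 and 0.00611. It also passed with the mean of a gene's probes (0.0461) and with pairs A and B only (0.039). The median was -0.01 without WT replicate C (adjusted p = 0.411), 0.08 without KO replicate B (adjusted p = 0.586) and 0.03 with array weights (adjusted p = 0.222). Cholesterol biosynthesis genes had a median of 0.08 over 10 members (adjusted p = 0.267), with Fdps at 0.43 (SE 0.30) and Dhcr7 at 0.23 (SE 0.34). The median of that list ranged from 0.007 to 0.10 when an array was omitted. In these lists 0 members passed over all genes or adjusted over the list alone in limma, and 2 growth factor genes and 1 Wnt gene had an unadjusted p under 0.05. The sex chromosome check found all 4 Xist probes detected on all 6 arrays, and 7 of 8 Y-linked probes on none.

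Over all 22 lists with at least 5 tested members, camera with a preset correlation of 0.01 called 10 and called 0 with an estimated correlation, where the lowest adjusted p was 0.425. With the pair letter as a replicate block these counts were 12 and 0. A high correlation of members does not explain every lost call. The list of matrix metalloproteinases and branching genes had an estimated correlation of -0.009, below the preset 0.01. Its adjusted p still went from 0.01 to 0.425. With an estimated correlation, 2 lists had an unadjusted p under 0.05 without the pair term and 0 with the block. The 0 calls in that setting therefore do not show that no list differed. Fry, which asks whether the genes of a list move one way, called 0 lists (lowest adjusted p = 0.324), with 2 at an unadjusted p under 0.05. Its mixed test, for change in either direction, called 1, the KDM5 list that holds Kdm5b.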

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

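Pairs A and B only, and the 50 Mb window at an unadjusted p under 0.01, were tests chosen after the results were seen. The count of 3 changed genes became 1 without background correction, 1 on the authors' value table and 1 with an offset of 50, and in each the gene was Csrp1. It became 0 in limma with detection p under 0.01 on all 6 arrays, a filter that by construction leaves out Kdm5b, Csrp1 and Cops8, with 237 genes at an unadjusted p under 0.05. Omission of an array gave 1 to 2 genes, with 1 each without WT replicate A, WT replicate B and KO replicate B. The Csrp1 call held in all 17 alternatives that tested it, with log2 changes of 4.84 to 7.20 and limma adjusted p from 4.14e-06 to 0.00493.

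Kdm5b missed the threshold without background correction (-0.87), on the authors' table (-0.89) and with an offset of 50 (-1.44), settings that draw dim values together. It also missed the threshold in every omission of a single array except WT replicate C, with log2 changes from -2.57 to -2.34 over the omissions. The list count of 10 became 0 with an estimated correlation and 7 to 13 when an array was omitted. The odds ratio near Kdm5b missed the threshold without background correction (2.12), on the authors' table (2.12), without a detection filter (1.38), with detection p under 0.01 on all 6 arrays (1.81) and with array weights (1.56), and the cause was not tested. It ranged from 1.68 to 4.80 when an array was omitted, and missed the threshold without KO replicate A, KO replicate C or WT replicate C. The immune list median was -0.00079 with pairs A and B only and ranged from -0.32 to 1.08 when an array was omitted, with -0.32 without KO replicate C. The epithelial-mesenchymal transition list ranged from -0.0095 (without KO replicate B) to 0.28. The mean correlation within pairs, 0.52, ranged from 0.0517 (without KO replicate C) to 0.647, and was 0.0768 without WT replicate C.

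With the pair letter as a replicate block the same 3 genes were called, Kdm5b stayed at -2.46 (limma adjusted p = 0.00729), the odds ratio was 2.20 (Fisher's exact p = 0.00457) and 12 lists were called. The list calls that differed stand with the lists, and the block changed no other call. Of 1227 values of named genes under the alternatives, 0 reversed a call, 19 lost and 2 gained a call, and 15 differences that had not passed changed sign. Of 396 list values, 31 lost and 19 gained a call in the same direction, 3 called ones changed sign, 4 uncalled ones passed with the opposite sign, and 18 others changed sign without passing. The 4 were the inflammatory list with array weights (-0.44), with pairs A and B only (-0.24) and without WT replicate C (-0.55, the lowest of a range up to 0.69 when an array was omitted), and the luminal progenitor and alveolar list with median scaling (-0.027), where camera still gave higher relative to other genes. The largest shift of the median over all genes was 0.084 on the log2 scale. Dim probes limit the folds, since Kdm5b in KO and Cops8 in WT were at background, and Nckap5 was detected on only 1 of 3 KO arrays.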

Other observations

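Tests of the windows beyond 20 Mb, the other probes, the cell type explanations and the other splits of the arrays were chosen after the results were seen, while the 20 Mb test was fixed before. Wap, Csn2 and Csn1s1, milk protein genes of secretory alveolar cells, had higher values in the KO array of every pair, while the casein gene Csn3 differed by -0.05, 0.19 and -0.26 in pairs A, B and C. In their list, the luminal progenitor and alveolar one, 10, 17 and 6 of 18 members were positive in pairs A, B and C. Wap read 6.72, 6.09 and 6.71 in WT and 12.87, 9.52 and 7.18 in KO for pairs A, B and C, a difference of 3.35 (SE 1.25), and Csn1s1 differed by 1.05 (SE 0.28). Neither passed adjusted over the list alone (limma adjusted p = 0.189 and 0.0605), and with the pair letter as a replicate block both did (0.0378 and 0.0353). These genes, and the lymphocyte and cycle genes of the next paragraph, were named after their values were seen.

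Single KO arrays carried their own shifts. In pair C the T-cell receptor component genes Cd3e and Cd3g read 9.78 and 10.30 in KO against 6.53 and 6.96 in WT, and the leukocyte gene Coro1a read 10.98 against 8.19. In pair A the cell cycle genes Top2a and Mcm5 read 8.18 and 9.93 in KO against 4.95 and 6.93 in WT, whereas in pair B they read 5.01 and 7.06 against 5.91 and 7.51. In pair B the endothelial genes Pecam1 and Vwf read 10.18 and 11.31 in KO against 8.92 and 10.31 in WT. Each is a single array against its partner, with no test.

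Genes at an unadjusted p under 0.05 were over-represented near Kdm5b, with 8 within 20 Mb and 329 elsewhere. DNA of another mouse strain carried with the targeted allele may contribute, and the 20 Mb test was fixed before for that reason (odds ratio 2.50, Fisher's exact p = 0.0205). The sources used here do not give the strains, and such DNA goes with the genotype, so it stays open. Genes 20 to 50 Mb away also showed an excess, where 17 of 213 (7.98%) had an unadjusted p under 0.05 against 3.09% elsewhere. The odds ratio was 2.72 (95% interval 1.53 to 4.53, Fisher's exact p = 0.000473). That window was chosen after the results were seen, the exact test takes genes as independent, and the other splits were not run for it. Whether an effect is limited to genes within 20 Mb is therefore not settled. Of the 25 genes at an unadjusted p under 0.05 within 50 Mb, 8 had other tested probes. Sequence variants under single probes are argued against only for these 8 as a set. Their other probes moved with the main probe by a mean of 0.46 on the log2 scale (7 of 8 in its direction, exact sign-flip p = 0.0234). The mean size at the main probe was 0.84. Those of Eif4e2 did not move with it, and those of Pfkfb2 and Armc9 moved by 0.13 and 0.22 where the main probes differed by -0.74 and -0.92. A mean over genes cannot decide for any single gene. Elsewhere the other probes of 96 of 108 such genes moved alike, by a mean of 0.36, so this is not particular to the window. Only Pfkfb2 and Plekha6 of the 8 lie within 20 Mb, too few for a test of their own. For the 17 genes with 1 probe, Csrp1 and Cops8 among them, variants and expression cannot be told apart because no other probe was tested. The 10 splits of the 6 arrays are too few for a share under 0.05: 2 splits gave as low a p, the real one at 0.0205 and another, WT A, WT B and KO C against the rest, at 0.00126.

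The fibroblast list had higher and the hormone-sensing and pan-luminal lists had lower medians in KO. Their camera calls were lost with an estimated correlation (adjusted p = 0.425, 0.425 and 0.434), a setting in which no list was called. In pair B the fibroblast and pan-luminal medians were 0.02 and -0.04, and the luminal progenitor and alveolar list did not share the direction (median 0.08). A lower share of luminal cells may contribute, and would raise basal genes alike. The fibroblast list exceeded the basal list by 0.50 in median log2 difference (permutation p over genes = 0.001), but genes of a list move together. A gap between the list medians taken within each array differed by 0.37 between KO and WT (95% interval over arrays -0.11 to 0.85). From the medians of the KO minus WT differences the gap was 0.66, 0.02 and 1.01 in pairs A, B and C, and it was 0.22 without WT replicate C and 0.75 without WT replicate B, so the arrays cannot tell. More fibroblasts in the KO cultures may contribute and cannot be told apart from changed expression, because 1 of the 4 most abundant members, Dcn at 0.11 (95% interval -0.28 to 0.49), lay below the list median while Mmp2 (0.09), Col6a1 (0.78) and Lum (0.70) had intervals that include it, and 17 of 18 members were detected on every WT array and 2 are in another list. An effect of genotype within cells is likewise open. Of the 10 splits, too few for a share under 0.05, 2 called as many lists, the real one with 10 and the highest other with 10.

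Counts of genes were also set against the other splits of the arrays, again too few for a share under 0.05. At an adjusted p under 0.05, 2 of the 10 splits gave as many genes as the real 3, and the highest other, which sets WT A, WT B and KO B against KO A and pair C, gave 274. At an unadjusted p under 0.05, 5 splits gave as many as the real 338, with 2497 as the highest other, which points to a structure of the samples that follows pair C. Among the 4 splits that part all 3 pairs, the real one had the most genes, 3 and 338, and the others had 0 and 60 to 125, or with the pair as a replicate block 904 against 255 to 576.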
